A study of Rattus norvegicus with 4 samples.

How the data were processed

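RNA was measured on Affymetrix rat expression arrays in hippocampal neural progenitor cells, with 1 array for each of 4 groups: KHS101 at 5 uM, KHS101 at 1.7 uM, retinoic acid at 1 uM with forskolin, and DMSO. Per the labels' protocols, cells of early passage were plated at 1000 cells per square centimetre in medium with N2 supplement, and compounds were present for 4 days; the protocol covers several experiments, DMSO was at 0.1%, and the forskolin concentration is not given in the sources used here. Total RNA was extracted on columns, its integrity was examined by microfluidic electrophoresis, and amplified biotin-labelled RNA was hybridised, per the labels' protocols.

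The deposited values are log2 expression values for 31099 probe sets on each of the 4 arrays. GCRMA and R 2.6.2 are named for them, per the submitters' processing notes, without a version of GCRMA, a statement of which step each served, or a genome build. The log2 scale was taken from the values, whose medians per array lay between 3.67 and 3.76 and whose maximum was 16.1. At equal ranks the 4 sorted columns differed by a median of 0.06 and at most 0.19, so the arrays had been brought to nearly the same distribution, and a change of all genes in 1 direction could not be seen in such values. GCRMA gives probe sets without specific signal low values whose differences have no meaning. Values under a floor of log2 = 5 were therefore raised to it; between 45.4% and 45.9% of probe sets lay above the floor.

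Of 31042 probe sets that are not array controls, 20826 had 1 gene symbol in the platform annotation, 436 had several and 9780 were unnamed here. Gene identifiers of 20758 of the named probe sets matched a RefSeq gene table, and no symbol needed an update. The 57 control probe sets, those with several genes and those without a name entered no gene count, so some members of the gene lists were not analysed here. A gene took the probe set with the highest mean over the 4 arrays, which gave 14217 genes, 4525 of them with 2 or more probe sets. No coordinates were used.

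The 6 comparisons were each treatment against DMSO, the KHS101 concentrations against each other, and each of them against retinoic acid with forskolin. A gene counted as measured if at least 1 of the 2 arrays was above the floor, and was called higher or lower at a log2 difference of at least 1 in size (2-fold). Where 1 of the 2 arrays was at the floor, the difference is a lower bound. No test was run, because no group has a replicate. The other probe sets of a gene were the sole repeat measurement: for the called genes with 2 or more probe sets above the floor, 326 of 326 other probe sets differed in the same direction for KHS101 5 uM, 167 of 168 for KHS101 1.7 uM and 178 of 186 for retinoic acid with forskolin. Of these, 71.8%, 73.2% and 62.9% passed 2-fold, and 0 passed it in the opposite direction. They share the RNA and the array, so they cover probe noise only.

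There were 25 gene lists, set before the data were examined, for neuronal, glial and progenitor identity, other cell types the cultures could hold, cell cycle, signalling and stress responses, metabolism and reference genes. For each list the measured members called higher and lower were counted, and the median difference was placed among 10000 random lists of the same size drawn from measured genes in the same of 10 bins of mean expression. A list outside the middle 95% of the random lists is said to stand apart, which describes these arrays and is not a p-value; a minimum of 3 measured genes for this was added after the data were seen. Overlaps between comparisons that share the DMSO array were set beside the overlap of independent lists and beside 100 sets of simulated unchanged arrays. The simulated noise was drawn from the difference of the KHS101 arrays within the bins of expression and so includes any effect of dose. These arrays were the pair most alike, so a wider spread between cultures was not simulated. The number of calls was not matched to the real lists, and equal noise on each array sets the simulated r in advance.

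Genes named in the Results followed a rule set before the data were examined. Members of the stress subsets named in the closing section did not, as those subsets were chosen after the results were seen. For each comparison with DMSO it took the 10 genes with the largest difference in each direction among those above the floor on both arrays and the 5 largest bounds; for the other comparisons it took the 5 largest. It added up to 4 members of each list that stands apart in the direction of its median and up to 2 called members in the other direction. It also took the largest shared differences (10 each way for both KHS101 concentrations, 5 each way for all 3 treatments and for opposite calls) and 22 genes always given. The text names most of these genes and leaves others out for length. Bag3 was named for KHS101 because the rule took it for retinoic acid with forskolin.

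Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots matplotlib 3.10.9. The steps were tested on simulated data made from the 8421 measured genes of a simulated KHS101 5 uM against DMSO comparison, with noise of 0.2 (SD, log2): 54% of genes changed by 2-fold were called, 96% of those changed by 2.83-fold and 100% of those changed by 4-fold, and 0.05% of unchanged genes. Of 200 lists of 20 unchanged genes, 5.5% lay outside the middle 95% of the random lists. The changed genes were all drawn from genes well above the floor in DMSO, so these rates do not hold for genes near it. The noise was a chosen value. Between the KHS101 arrays the difference had an SD of 0.37 for genes above the floor on both, any effect of dose included. The 0.05% is therefore not an error rate for these arrays.

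The alternatives were a floor of 4 or 6 or none, a 3-fold threshold, the mean of all probe sets of a gene, leaving out probe sets that can match several transcripts, shifting each array to a median difference of 0, loess on the mean level (span 0.4), quantile normalization repeated, and leaving out list members held by more than 1 list. The control probe sets for spiked RNA, 42 in number, were higher than in DMSO by a median of 0.27, 0.49 and 0.33 for KHS101 5 uM, KHS101 1.7 uM and retinoic acid with forskolin, and were not used for scaling.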

Results

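Gene expression was measured in rat hippocampal neural progenitor cells, which divide in culture and can form neurons or glia. The cells had been kept with KHS101, a small molecule studied for its effect on neuronal differentiation, at 5 uM or 1.7 uM, with the solvent dimethyl sulfoxide (DMSO) as negative control, or with 1 uM retinoic acid together with forskolin as positive control. Forskolin activates adenylyl cyclase; its concentration is not given in the labels, and the series design names retinoic acid alone for this control. Each of the 4 groups was a single Affymetrix array, so the differences below have no replicate check, no p-value could be computed, and the number of arrays limits the precision of every value. On each array between 8389 and 8471 of the 14217 named genes lay above the floor of log2 = 5 that was set as the limit of specific signal. A gene was called higher or lower at a difference of at least 2-fold, and a difference from an array at the floor is given as a lower bound ("at least"). Pearson's r over all probe sets was 0.996 between the KHS101 arrays and between 0.981 and 0.992 for all other pairs; probe sets are not independent replicates. The 12 measured reference genes had a median log2 difference from DMSO between -0.04 and 0.02, and none of them differed from DMSO by 2-fold. Against retinoic acid with forskolin, 1 of the 12 was lower at each KHS101 concentration. The 3' minus 5' difference of the beta-actin control probe sets was 1.54 on the KHS101 5 uM array, 1.40 at 1.7 uM, 1.37 with retinoic acid and forskolin and 1.26 in DMSO, and that of hexokinase was 0.96, 0.80, 0.66 and 0.69 in the same order.

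KHS101 at 5 uM was compared with DMSO to ask which genes the compound moved at the higher concentration. Trib3, a pseudokinase induced by the transcription factor ATF4, was 136-fold higher, with log2 values of 12.84 against 5.75. Hmox1 (heme oxygenase 1) was 43.5-fold higher, Srxn1 (sulfiredoxin) 38.6-fold and Slc7a11, the cystine transporter, 29.5-fold. Mcm3, a subunit of the replicative helicase, was 13.1-fold lower, and its partner Mcm5 was 9.65-fold lower. In total 526 of 8543 measured genes were higher and 692 were lower.

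Of 44 measured genes of the integrated stress and unfolded protein response, 30 were higher in KHS101 at 5 uM, 0 were lower and 14 were neither, with a median log2 difference of 1.39 (percentile 100 among 10000 random lists matched on expression). Nupr1, a stress-induced chromatin protein, was at least 32.6-fold higher and the transcription factor Atf3 at least 22.8-fold. Chac1, which degrades glutathione, was 22.4-fold higher and Ppp1r15a, a phosphatase subunit that reverses translational arrest, 19.0-fold. Cth, the cystathionine gamma-lyase of cysteine synthesis, had the largest bound, at least 82.8-fold. Among 22 measured genes of the oxidative stress and NRF2 response, 9 were higher and 0 lower (median 0.56, percentile 100). Besides Hmox1, Srxn1 and Slc7a11, the quinone reductase Nqo1 was at least 25.4-fold higher. Of 15 measured p53 response genes, 6 were higher and 1 was lower (median 0.68, percentile 99.99). Cdkn1a, which encodes the cell-cycle inhibitor p21, was 11.6-fold higher, Sesn2, which the integrated stress list also holds, 9.39-fold and Bbc3 4.92-fold, while Sesn1 was 2.48-fold lower. Hypoxia and ARNT-dependent genes numbered 8 higher and 1 lower of 34 (median 0.27, percentile 99.83): the glycolytic regulator Pfkfb3 was 15.7-fold higher and Vegfa 12.4-fold, and Mxi1 was 2.21-fold lower. Outside these lists, the interferon-inducible Ifi27l2b was 72.8-fold higher, Dhrs3, a retinaldehyde reductase, 34.5-fold, the hyaluronan receptor Cd44 16.6-fold and Fam13c 15.8-fold. Klf4 and Gadd45b, which were at the floor in DMSO, were at least 35.4-fold and 30.5-fold higher.

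Of the 50 measured genes of DNA replication and S phase, 47 were lower in KHS101 at 5 uM and 0 were higher (median -2.24, percentile 0). E2f1, a transcription factor of the G1 to S transition, was 9.45-fold lower and the thymidine kinase Tk1 9.34-fold. Among 53 mitosis and centrosome genes, 45 were lower and 0 higher (median -1.42, percentile 0), with Melk 6.02-fold lower, Foxm1 5.62-fold, Spc25 4.58-fold and Mad2l1 4.35-fold. E2f7 was 9.58-fold and the centromere gene Cenpu 9.45-fold lower. Among genes above the floor on both arrays, the largest difference downward was Armh4, 17.3-fold, followed after Mcm3 by Mlf1 at 10.1-fold and the potassium channel subunit Kcnmb4 at 9.86-fold. Nid2, Ackr3, Sytl2, C1ql1 and Lrrc4 were at the floor with KHS101 and at least 11.1-fold, 10.7-fold, 10.6-fold, 9.87-fold and 8.51-fold lower.

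Oligodendrocyte lineage genes were also lower in KHS101 at 5 uM. Of 13 measured, 9 were lower and 0 higher (median -1.18, percentile 0); the sulfotransferase Gal3st1 was 4.72-fold lower, myelin basic protein Mbp 4.32-fold, Nkx2-2 3.13-fold and Ugt8 3.09-fold. Apod, a lipid carrier of glia, was 9.17-fold lower. The astrocyte list had a median of -0.48 over 9 measured genes (1 higher, 2 lower, percentile 1.70): Ndrg2 was 2.85-fold and Aldoc 2.77-fold lower, and Cd44 was the higher gene. In the progenitor and radial glia list, 3 of 17 genes were higher and 4 lower (median -0.33, percentile 0.84). Sox3 was 4.94-fold lower, Fabp7 4.33-fold, Notch1 2.74-fold and Lhx2 2.07-fold, whereas cyclin D2 (Ccnd2) was 4.56-fold higher and Tnc at least 4.03-fold. Only 5 fibroblast and meningeal genes were measured (2 higher, 1 lower, median 0.79, percentile 98.75): Postn was at least 3.48-fold and Igfbp4 2.28-fold higher, and Pdgfra, which the oligodendrocyte list also holds, was 2.10-fold lower. The lists of immature neurons (median 0.13, percentile 84.3, 1 of 14 higher) and mature neurons (median 0.14, percentile 83.4, 5 higher and 1 lower of 19) lay within the middle of the random lists. At a 3-fold threshold 218 genes were higher and 300 lower. The places of the progenitor, astrocyte and fibroblast lists depended on the floor: without one their medians were 0.0164, 0.0185 and 0.0184.

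**Figure D1:**
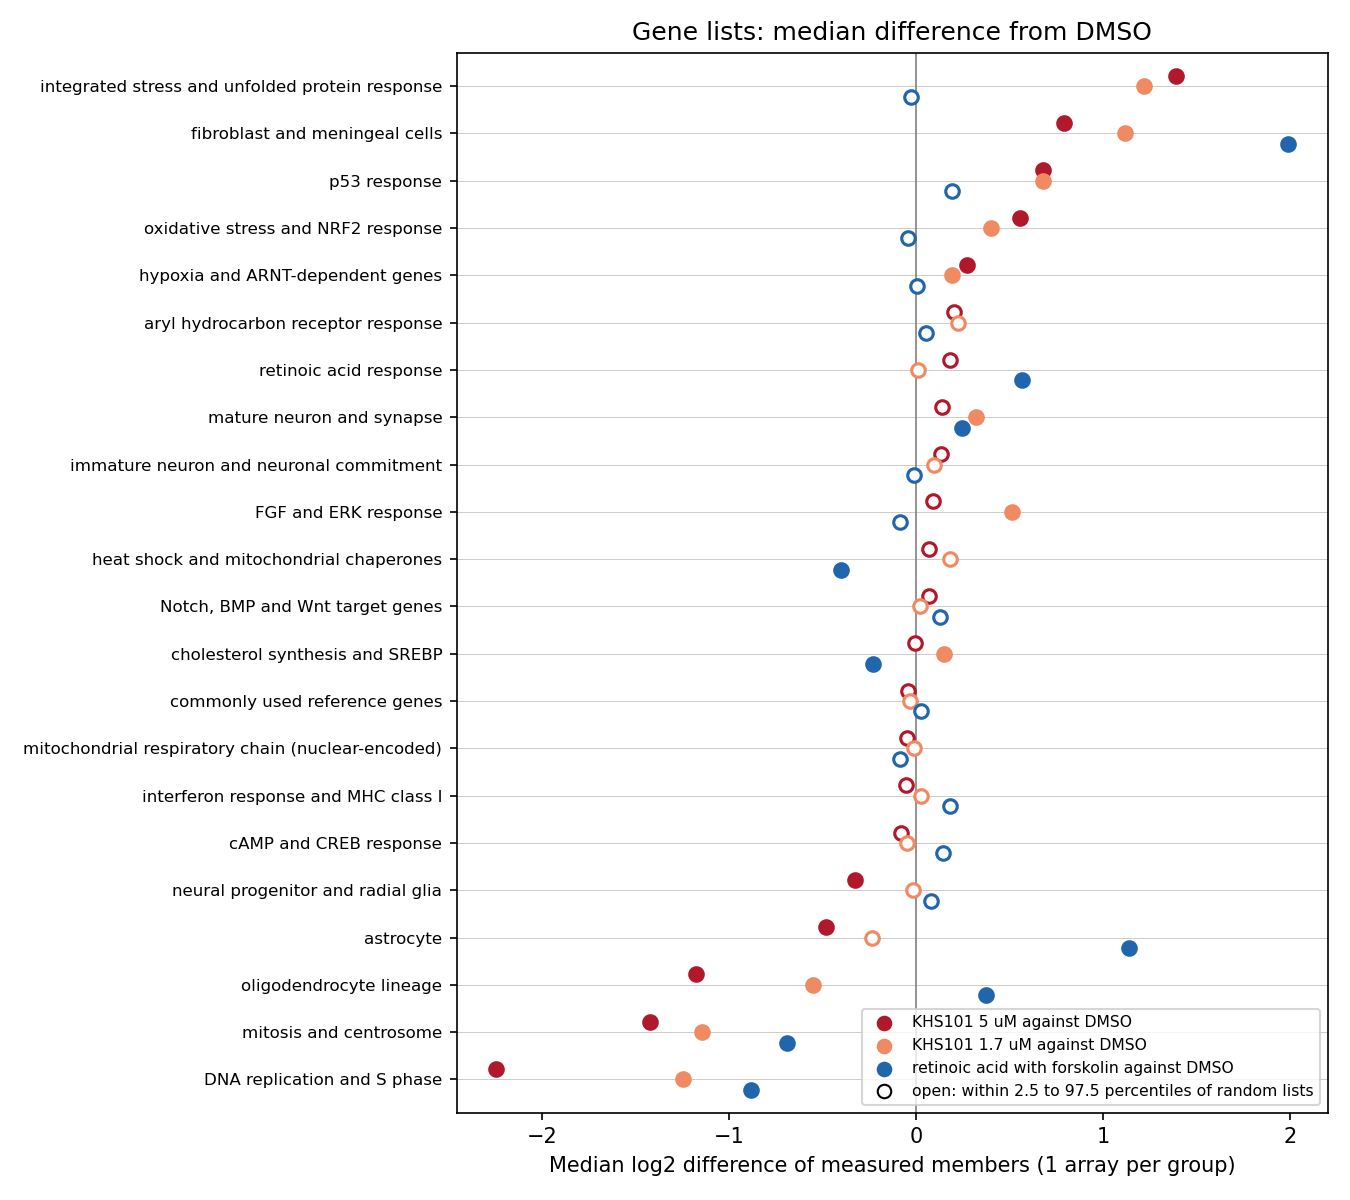
Median log2 difference from DMSO of the measured members of each gene list with 3 or more measured genes, for KHS101 5 uM, KHS101 1.7 uM and retinoic acid with forskolin. Filled points lie outside the middle 95% of 10000 random lists; the integrated stress list sits at 1.39 and 1.22 with KHS101 and at -0.03 with retinoic acid and forskolin, and the replication list at -2.24, -1.25 and -0.88.

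The same comparison was made for KHS101 at 1.7 uM. Among genes above the floor on both arrays, Trib3 again had the largest difference, 68.0-fold higher, followed by Ifi27l2b at 46.1-fold, Dhrs3 at 30.7-fold and Slc7a11 at 22.4-fold. Chac1 was 15.2-fold higher, the sorting receptor Sorcs2 14.2-fold, Srxn1 9.66-fold, Cd44 9.56-fold, Stac2 8.90-fold and Atf5, a transcription factor of the stress response, 8.68-fold. C1ql1, a secreted synaptic organiser, was 8.66-fold lower, the chemokine receptor Ackr3 7.86-fold, Lrrc4 7.20-fold, the basement membrane gene Nid2 6.88-fold and Armh4 6.66-fold. Bmp4 and Casp6 were 5.72-fold and 5.75-fold lower, Itga8 4.34-fold and Sytl2 4.35-fold. Over all genes 372 of 8533 were higher and 364 lower.

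The integrated stress list had 26 genes higher and 0 lower of 44 at 1.7 uM (median 1.22, percentile 100), and the NRF2 list 8 higher and 0 lower of 22 (median 0.40, percentile 99.99), with Hmox1 8.40-fold higher. Cdkn1a was 7.99-fold higher in a p53 list with 4 of 14 genes higher (median 0.68, percentile 100), and Gadd45a was 2.90-fold higher. Pfkfb3, Vegfa, Gys1 and Ddit4 led the hypoxia list at 7.68-fold, 6.67-fold, 3.46-fold and 3.15-fold (6 of 31 genes higher, 0 lower, median 0.19, percentile 99.23). Cth, Nupr1, Cd93, Klf4 and Nqo1 had the largest bounds, at least 51.8-fold, 16.8-fold, 15.1-fold, 11.9-fold and 11.9-fold higher. Replication genes were lower in 39 of 50 cases (median -1.25, percentile 0) and mitosis genes in 38 of 53 (median -1.14, percentile 0), with 0 higher in either list; Clspn was 4.39-fold, Orc1 3.79-fold, Cdca2 3.56-fold and Kif20b 3.48-fold lower. The largest bounds downward were Mx2, at least 7.33-fold, Txnip 7.02-fold, P2ry12 6.32-fold, Olfml2a 4.76-fold and Lgr5 4.66-fold. Oligodendrocyte lineage genes had a median of -0.55 (3 of 13 lower, percentile 0.01), with Mbp 2.90-fold lower. The mature neuron list stood apart here with 5 genes higher and 1 lower of 18 (median 0.32, percentile 99.60). Gad1, which makes the transmitter GABA, was at least 4.12-fold higher, the neuronal enolase Eno2 3.44-fold, the postsynaptic scaffold gene Dlg4 2.59-fold and Camk2b 2.58-fold, and the sodium channel gene Scn3a was 2.40-fold lower. The FGF and ERK response list also stood apart (3 of 15 higher, 0 lower, median 0.51, percentile 100; Egr2 at least 4.35-fold, Ier3 2.34-fold and Egr1 2.30-fold), as did cholesterol synthesis with a median of 0.15 and 0 of 29 genes past 2-fold. Fibroblast markers had 3 of 5 genes higher (median 1.12, percentile 99.93), with Postn at least 6.86-fold and Col5a1 4.77-fold. At a 3-fold threshold 146 genes were higher and 68 lower. The FGF, cholesterol, mature neuron, hypoxia and fibroblast lists each came within the middle of the random lists under 1 or more alternative settings.

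The next question was how far the genes moved at both KHS101 concentrations were the same and followed the dose. Of the genes measured in both comparisons, 314 were higher and 345 lower at both concentrations, and 0 were called in opposite directions. Independent lists would share 22.6 and 29.6 genes. Simulated unchanged arrays sharing the DMSO array, not matched for the number of calls, shared 23.2 and 27.8. The differences correlated across genes with r = 0.90 and a covariance of 0.44, and genes are not independent replicates. The simulated arrays had a covariance of 0.07, and their r of 0.50 follows from equal noise on arrays with a shared control. With only 1 DMSO array, part of this overlap may come from that array. The pair of differences that share no array, KHS101 5 uM minus retinoic acid with forskolin and KHS101 1.7 uM minus DMSO, had r = 0.59. Trib3, Cth, Ifi27l2b, Dhrs3, Slc7a11, Nupr1, Chac1, Sorcs2, Cd93 and Klf4 had the largest differences or bounds upward at both concentrations, and C1ql1, Ackr3, Mx2, Lrrc4, Txnip, Nid2, Armh4, P2ry12, Casp6 and Bmp4 downward.

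Among the 314 genes higher at both concentrations, 243 (77.4%) were further from DMSO at 5 uM, with median log2 differences of 1.81 and 1.53, and among the 345 lower genes 302 (87.5%) were, with medians of -1.84 and -1.29. Between the KHS101 arrays 69 of 8500 genes were higher and 147 lower at 5 uM. Hspa1a, an inducible heat shock protein, was 6.39-fold higher at 5 uM than at 1.7 uM, Hmox1 5.18-fold and the aldo-keto reductase Akr1b8 4.68-fold. Nfatc2 was 3.88-fold lower, Sez6 3.74-fold, Myl9 3.66-fold, Mcm5 3.52-fold and Col9a1 3.51-fold. Replication genes were lower at 5 uM in 20 of 50 cases (median -0.87, percentile 0), mitosis genes in 2 of 53 (median -0.29, percentile 0), and oligodendrocyte lineage genes in 1 of 12 (median -0.60, percentile 0), with 0 higher in these lists. Also with lower medians were the progenitor list (-0.25, 0 of 17 past 2-fold, percentile 0.09), cholesterol synthesis (-0.185, 1 of 29 lower, percentile 0.12) and the fibroblast list (-0.80, 1 of 4 lower, percentile 0.03). Lists with higher medians at 5 uM were integrated stress (0.21, 5 of 44 higher, percentile 100), NRF2 (0.19, 4 of 22 higher, percentile 99.95), heat shock (0.17, 1 of 19 higher, percentile 99.77) and FGF and ERK response (0.16, 0 of 15 past 2-fold, percentile 98.87). At a 3-fold threshold these 2 arrays differed at 12 genes upward and 17 downward.

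**Figure D2:**
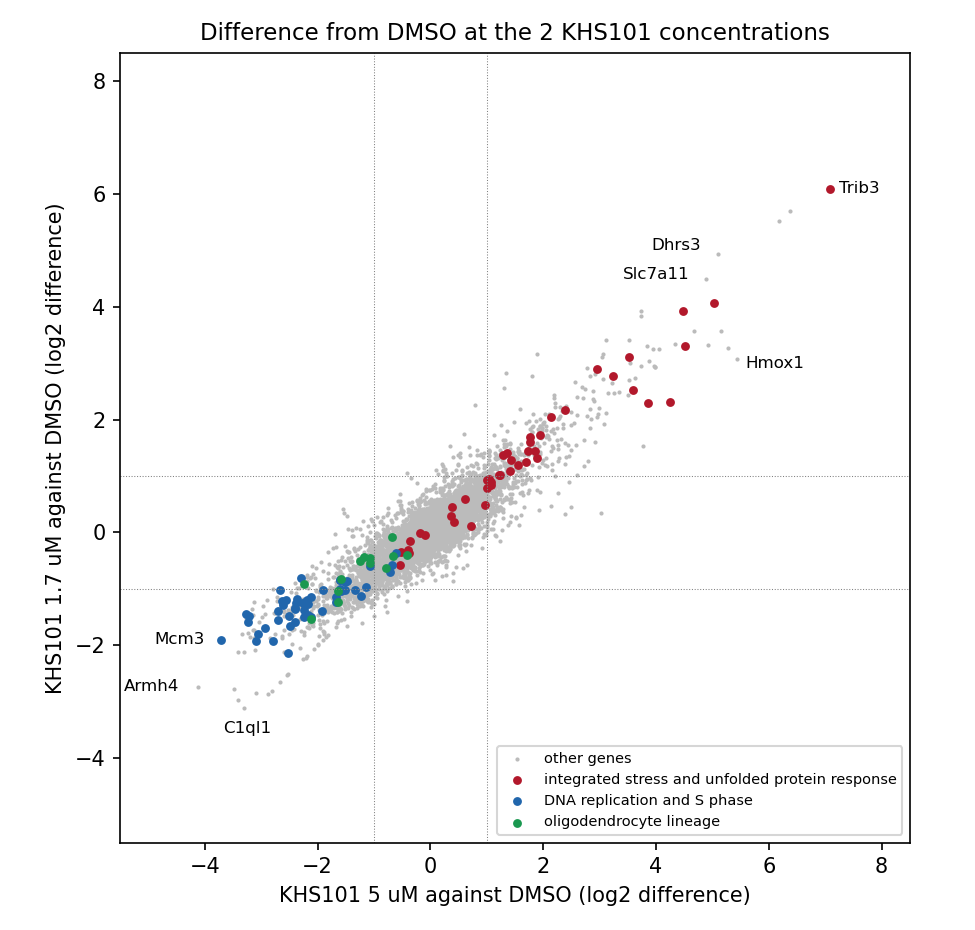
Log2 difference from DMSO of each gene at 5 uM (x axis) and 1.7 uM (y axis) KHS101, for genes measured in both comparisons, with values under the floor raised to it. Points of the integrated stress list lie to the upper right (Trib3 at 7.09 and 6.09) and those of the replication list to the lower left (Mcm3 at -3.71 and -1.91); dotted lines mark 2-fold.

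Retinoic acid with forskolin was compared with DMSO as the positive control. Mgp (matrix Gla protein) was 245-fold higher, Dhrs3 156-fold and the chemokine Ccl2 44.2-fold. Cyp26a1, the enzyme that clears retinoic acid and a direct target of its receptors, was at the floor in DMSO and at least 104-fold higher. In total 370 of 8535 genes were higher and 269 lower.

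Retinoic acid response genes numbered 5 higher and 0 lower of 12 with retinoic acid and forskolin (median 0.57, percentile 99.98); the receptor gene Rarb was 7.13-fold higher and the corepressor Nrip1 2.67-fold. Among 9 astrocyte genes 6 were higher and 2 lower (median 1.14, percentile 100): Cp was 6.90-fold, Fgfr3 2.52-fold, Ndrg2 2.45-fold and Hepacam 2.34-fold higher, and Id3 was 3.46-fold and Cd44 2.07-fold lower (the other measured probe set of Cd44 differed by -0.057). Oligodendrocyte lineage genes were higher in 4 of 14 cases and lower in 0 (median 0.37, percentile 99.90), with Fa2h 5.85-fold, Mbp 2.44-fold, Myrf 2.18-fold and Gal3st1 2.01-fold higher. In the mature neuron list 3 of 18 genes were higher and 1 lower (median 0.24, percentile 98.30). Dlg4 was 3.86-fold, Ndrg4 2.26-fold and the glutamate receptor subunit Gria2 2.16-fold higher, and Camk2b was 2.22-fold lower. Dlg4 rested on 1 of 2 measured probe sets: the other differed by 0.0077 here and by -0.018 with KHS101 at 1.7 uM. The immature neuron list had a median of -0.01 (2 higher, 1 lower of 16, percentile 48.8). Fibroblast markers were higher in 3 of 5 cases (median 1.99, percentile 99.98), Mgp and Col5a1 (5.32-fold) among them, and Ccl2 was the single measured gene of the microglia and macrophage list. Tesc, Synpo, Ccl7 and Egr2 were at the floor in DMSO and at least 44.6-fold, 32.3-fold, 18.1-fold and 15.7-fold higher. Slc15a2 was 14.7-fold higher, the microtubule-associated kinase Dclk1 11.2-fold, Pmepa1 9.62-fold, Nrbp2 9.62-fold, Sorcs2 8.47-fold, Cdhr2 8.25-fold and Ak4 7.78-fold.

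Replication genes were lower in 17 of 50 cases with retinoic acid and forskolin (median -0.88, percentile 0), with Orc1 3.07-fold, Clspn 2.70-fold and Mcm3 2.24-fold lower, and mitosis genes in 5 of 53 (median -0.69, percentile 0), with Mad2l1 2.68-fold lower. The transcriptional repressor Tgif2 was 5.55-fold lower, Eef1akmt4 5.26-fold, Coro1a 4.68-fold, the Wnt target Lgr5 4.58-fold, Wwc1 4.47-fold and Pop1 4.40-fold; Ncs1 had the largest bound downward, at least 6.92-fold. Shq1 was 4.09-fold, Shmt1 3.94-fold, Sdc1 3.85-fold and Morc4 3.58-fold lower. Genes of heat shock and mitochondrial chaperones had a median of -0.40 (1 higher, 1 lower of 19, percentile 0.09), with Clpp 2.10-fold lower and Cryab 3.03-fold higher, and cholesterol synthesis genes a median of -0.23 with 0 of 29 past 2-fold (percentile 1.76). The integrated stress list had a median of -0.03, with 0 of 42 genes higher and 4 lower, and the NRF2 list a median of -0.04. At a 3-fold threshold 134 genes were higher and 34 lower. Without a floor the medians of the astrocyte, retinoic acid response and fibroblast lists were 0.0252, 0.0306 and 0.0225, within the middle of the random lists, and the mature neuron list came within it under 3 alternatives.

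KHS101 was then set against the positive control. With KHS101 at 5 uM and with retinoic acid and forskolin, 77 genes were higher in both and 97 lower in both, while 26 were higher with KHS101 and lower with retinoic acid and forskolin and 37 the reverse. Independent lists would share 19.9, 22.0, 15.3 and 28.7 genes in that order. Simulated unchanged arrays with a shared control, not matched for the number of calls, shared 23.2, 27.8, 0.17 and 0.17. The differences correlated with r = 0.20 and a covariance of 0.09, and at 1.7 uM with r = 0.34 and a covariance of 0.12. The simulated covariance was 0.07. The simulated r of 0.50 is set by equal noise on arrays with a shared control, so it does not measure how alike the treatments were. KHS101 5 uM minus 1.7 uM and retinoic acid with forskolin minus DMSO, which share no array, had r = -0.13. This pair covers only the step between the KHS101 concentrations, so it does not replace the correlations of the differences from DMSO. Dhrs3, Synpo, Sorcs2, Ccl2 and St3gal1 had the largest differences or bounds upward among the 69 genes higher in all 3 treatments. Lgr5, Chtf18, Mybl2, Plk5 and Orc1 had the largest among the 75 lower in all 3; Lgr5 was 4.61-fold lower at 5 uM and 4.58-fold lower with retinoic acid and forskolin. In contrast, 232 genes were higher and 256 lower at both KHS101 concentrations without a call for retinoic acid and forskolin. Slc6a15 was 4.81-fold higher at 5 uM and 3.38-fold lower with retinoic acid and forskolin, as was Tgif1 at 2.86-fold and 3.47-fold. The secreted factor Cytl1 was 6.96-fold lower and 5.33-fold higher, and the cell-cycle inhibitor Cdkn1c 5.83-fold lower and 4.23-fold higher.

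Directly compared, 769 of 8606 genes were higher and 880 lower in KHS101 at 5 uM than in retinoic acid with forskolin, and 509 of 8588 were higher and 463 lower at 1.7 uM. Hmox1 was 102-fold, Trib3 82.1-fold, Ifi27l2b 63.6-fold, Chac1 44.1-fold and Cd44 34.3-fold higher at 5 uM. Cytl1 was 37.1-fold, Cdkn1c 24.7-fold, Sez6 23.4-fold, Armh4 22.4-fold and Cdhr2 21.5-fold lower. Of 44 integrated stress genes 29 were higher and 0 lower in this comparison (median 1.80, percentile 100), of 50 replication genes 36 were lower and 0 higher (median -1.38, percentile 0), and of 14 oligodendrocyte lineage genes 12 were lower and 0 higher (median -1.54, percentile 0). The retinoic acid response list was lower in 4 of 12 cases (median -0.70, percentile 0.40) and the astrocyte list in 6 of 9, with 2 higher (median -1.65, percentile 0). At 1.7 uM 28 of 44 integrated stress genes were higher than with retinoic acid and forskolin (median 1.54, percentile 100) and 7 of 14 oligodendrocyte lineage genes lower (median -0.97, percentile 0), but only 2 of 50 replication genes were lower (median -0.42, percentile 0) and 2 of 53 mitosis genes (median -0.43, percentile 0), against 14 of 53 mitosis genes at 5 uM (median -0.79, percentile 0). At a 3-fold threshold 304 genes were higher and 360 lower at 5 uM, and 29 and 10 genes were higher and lower in both treatments against DMSO.

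**Figure D3:**
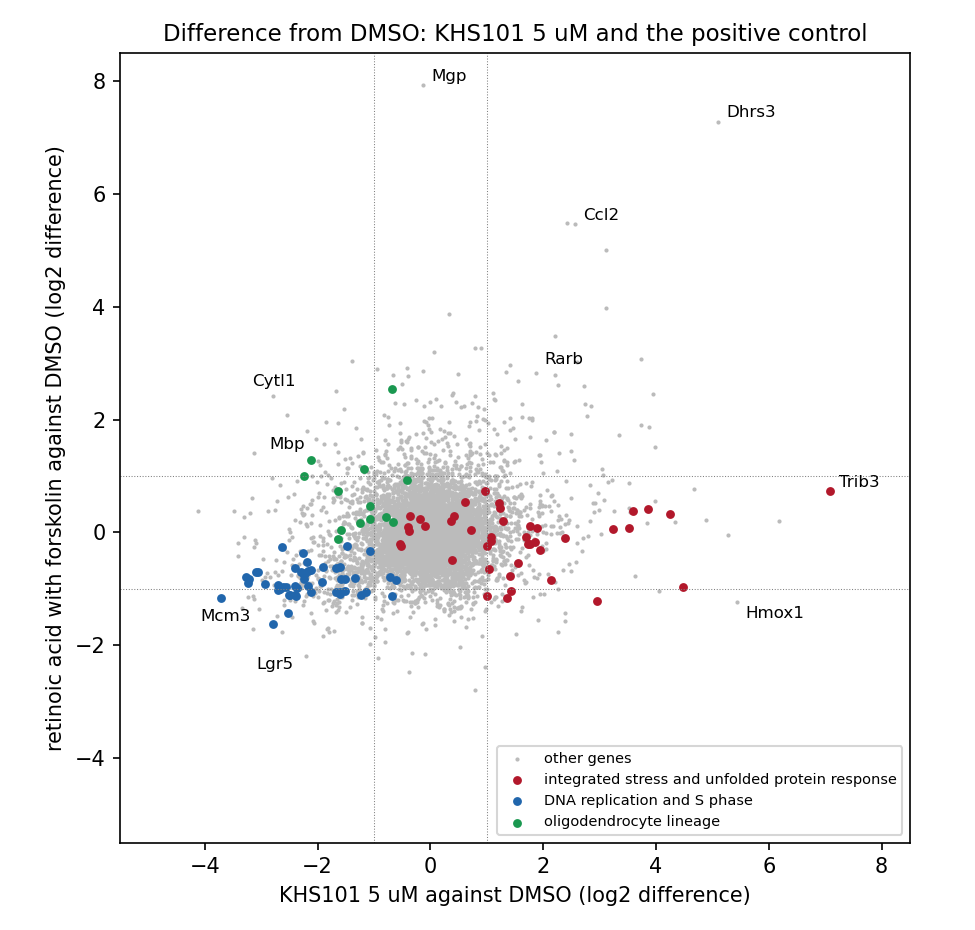
Log2 difference from DMSO of each gene with KHS101 5 uM (x axis) and with retinoic acid and forskolin (y axis), for genes measured in both comparisons, with values under the floor raised to it. Integrated stress genes spread along the KHS101 axis (Trib3 at 7.09 and 0.73), Dhrs3 lies high on both (5.11 and 7.28), and Mbp is lower with KHS101 (-2.11) and higher with retinoic acid and forskolin (1.29).

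The remaining lists lay mostly within the middle of the random lists. Among them, the nuclear-encoded respiratory chain had medians of -0.051, -0.010 and -0.086 over 43 genes for KHS101 5 uM, KHS101 1.7 uM and retinoic acid with forskolin, with 1 gene lower at 5 uM and no other call. In the same order, cAMP and CREB response genes had medians of -0.08, -0.05 and 0.14, Notch, BMP and Wnt target genes 0.07, 0.02 and 0.13, and interferon and MHC class I genes -0.06, 0.03 and 0.18. The 4 measured genes of the aryl hydrocarbon receptor response had medians of 0.20, 0.22 and 0.05. Heat shock and mitochondrial chaperones had 5 of 19 genes higher at 5 uM and 4 at 1.7 uM, with medians of 0.07 and 0.18 (percentiles 74.8 and 97.2), and 0 lower; Bag3 was 5.10-fold and 3.59-fold higher. FGF and ERK response genes at 5 uM had a median of 0.09 with 4 higher and 1 lower of 15, and cholesterol synthesis genes -0.01. KHS101 had retinoic acid response medians of 0.18 at 5 uM and 0.01 at 1.7 uM, each with 2 genes higher and 1 lower of 11. For the endothelial and mural list 1 gene was measured with KHS101 and 3 with retinoic acid and forskolin, and 0 of 9 ependymal and choroid plexus genes were measured in any comparison.

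A set of genes was given whatever their difference, because they mark the fates of these cells or were known in advance to bear on KHS101. Tacc3, which encodes a centrosome protein known as a target of KHS101, had log2 values of 9.83 at 5 uM, 10.03 at 1.7 uM, 10.45 with retinoic acid and forskolin and 11.28 in DMSO, which is 2.74-fold, 2.39-fold and 1.77-fold lower. Arnt2, a transcription factor that binds TACC3, was within 2-fold in all 3 treatments (differences of 0.46, 0.51 and -0.09), as was Arnt (-0.14, -0.06 and 0.20). The neuronal tubulin Tubb3 was 1.55-fold and 1.68-fold higher with KHS101 at 5 and 1.7 uM, short of 2-fold, and 2.20-fold higher with retinoic acid and forskolin; Map2 differed by 0.14, 0.21 and 0.32. Neurod1, Dcx, Gfap and Hes5 were not above the floor on any array. Mki67, a marker of dividing cells, was 2.39-fold and 2.34-fold lower with KHS101 and 1.23-fold lower with the positive control, and cyclin B1 (Ccnb1) was 2.39-fold, 2.10-fold and 1.83-fold lower. Sox2 was within 2-fold in all treatments (-0.44, -0.18 and -0.20), and Nes differed by 0.52, 0.61 and -0.69. Olig2 was 2.99-fold lower at 5 uM and 1.78-fold lower at 1.7 uM. S100b differed by 0.17, 0.28 and 1.05. Cyp26b1 was 8.68-fold and 3.66-fold lower with KHS101 and 1.20-fold lower with retinoic acid and forskolin, while Rarb was 3.65-fold and 3.93-fold higher with KHS101. Id1 was 1.92-fold higher at 5 uM and at least 1.79-fold lower with retinoic acid and forskolin. Hspd1, a mitochondrial chaperone, differed by 0.07, 0.18 and -0.53.

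**Figure D4:**
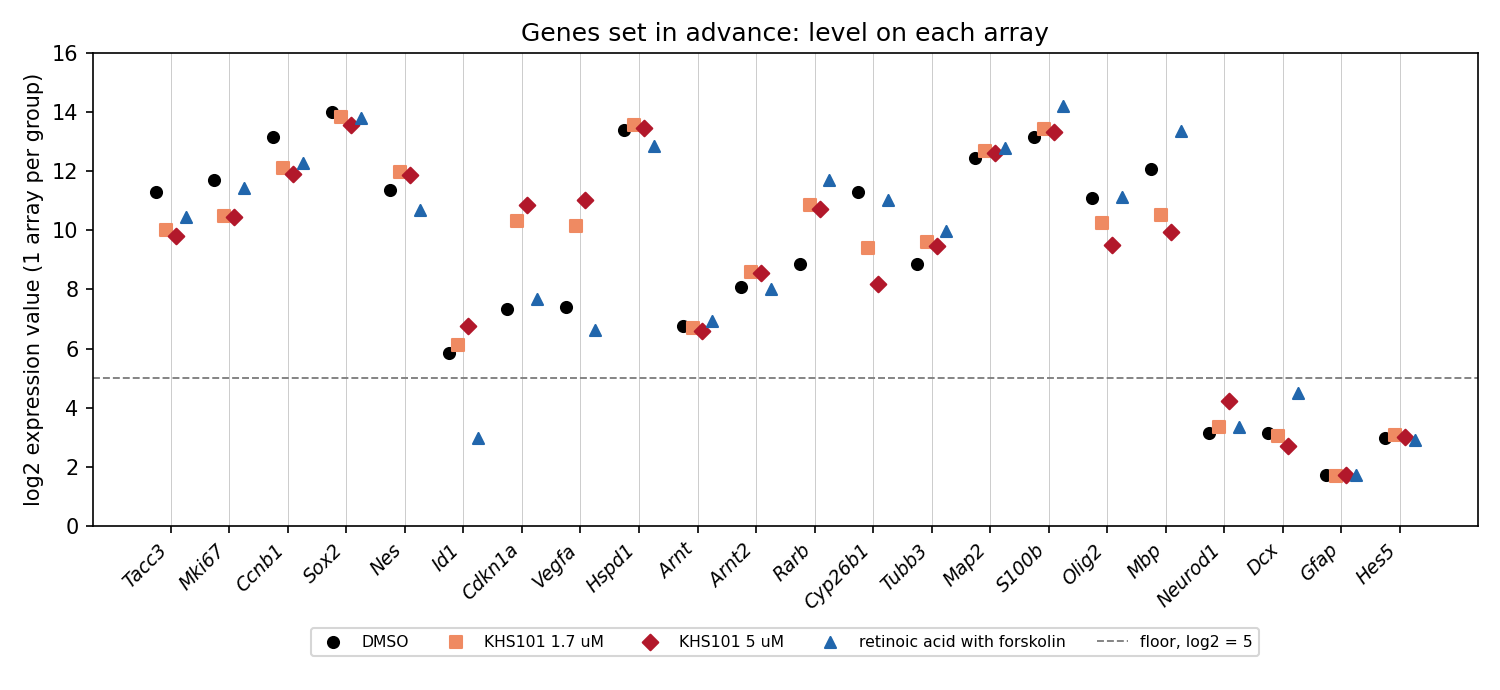
Log2 expression value of 22 genes set before the data were examined, on each of the 4 arrays (1 array per group); the dashed line is the floor of log2 = 5. Tacc3, Mki67 and Ccnb1 lie below DMSO on the 3 treated arrays, Cdkn1a and Vegfa lie above DMSO on both KHS101 arrays, and Neurod1, Dcx, Gfap and Hes5 lie under the floor on all 4.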

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

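The tests of explanations in this part were all chosen after the results were seen.

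The control probe set for 5S ribosomal RNA, which entered no comparison, had log2 signals of 7.89 with KHS101 at 5 uM and 5.27 at 1.7 uM, against 2.81 in DMSO and 2.54 with retinoic acid and forskolin; it drew attention because it was above the floor on the KHS101 arrays alone. A higher signal of all control probe sets is argued against, since the 42 spiked controls were higher by a median of 0.27 at 5 uM (from 0.14 to 1.26). RNA degradation in the KHS101 cultures stays open: the 3' minus 5' difference exceeded that of DMSO at 5 and 1.7 uM by 0.29 and 0.14 for beta-actin, 0.28 and 0.12 for hexokinase and 0.042 and 0.015 for GAPDH, against 0.11, -0.030 and 0.035 with retinoic acid and forskolin, and each value comes from 1 array. A difference in the labelling of RNA without a poly(A) tail, a difference between cultures and a biological change in 5S RNA all stay open and were not tested.

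Of the 9780 probe sets without a gene name here, 2504 were measured for KHS101 5 uM, 2482 for KHS101 1.7 uM and 2499 for retinoic acid with forskolin. Of the measured ones, 183, 143 and 167 were higher than in DMSO in that order, while 219, 111 and 54 were lower. They drew attention as signal outside the gene counts.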

How the results depend on the processing

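All alternatives were set before the data were examined. Of 153 recomputed counts, 136 stayed within 1.5 times the main count; the 3-fold threshold moved the other 17, as its construction implies. It gave 218 genes higher and 300 lower for KHS101 5 uM against DMSO, 146 and 68 for KHS101 1.7 uM, 134 and 34 for retinoic acid with forskolin, 12 and 17 between the KHS101 concentrations, 304 and 360 for KHS101 5 uM against retinoic acid with forskolin, and 169 and 151 for 1.7 uM. It left 134 genes higher and 66 lower at both concentrations, and for KHS101 5 uM and retinoic acid with forskolin 29 higher in both, 10 lower in both and 8 in opposite directions. No scaling alternative moved the share of calls that were higher by more than 10 percentage points.

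Of 600 recomputed list medians, 577 kept their place inside or outside the middle of the random lists. Those of them that stood apart also kept their sign, which was not compared for the others. Without a floor, which adds genes without specific signal, the medians of 4 lists that stood apart changed sign. These were mature neuron at 1.7 uM (-0.028), progenitor (0.016) and astrocyte (0.0185) at 5 uM, and fibroblast at 1.7 uM (-0.029). Also without a floor, the astrocyte (0.025), retinoic acid response (0.031) and fibroblast (0.0225) lists with retinoic acid and forskolin and the fibroblast list at 5 uM (0.0184) no longer stood apart, and heat shock genes at 1.7 uM did (0.18). For the following the cause was not tested. Lists that no longer stood apart were mature neuron with retinoic acid and forskolin at floor 6 (0.23), with loess (0.24) and with quantile normalization (0.20), progenitor at 5 uM at floor 4 (-0.21), fibroblast at floor 4 (0.064 at 5 uM, 0.45 at 1.7 uM), and at 1.7 uM hypoxia with the mean of probe sets (0.11), cholesterol with loess (0.14) and quantile normalization (0.0885), and FGF without shared probe sets (0.16). Lists that newly stood apart were retinoic acid response (0.37) and heat shock (0.18) at 1.7 uM with the mean of probe sets, heat shock at 5 uM at floor 4 (0.25), and Notch, BMP and Wnt targets with retinoic acid and forskolin at floor 6 (0.31). The integrated stress, NRF2, p53, replication, mitosis and oligodendrocyte lists kept their place in every alternative. Of 3186 recomputed differences of named genes, 3062 kept their side of 2-fold, 113 no longer passed the threshold, 11 newly passed it and 0 called differences changed sign. No paired analysis was possible because each group has 1 array, and signal near the floor limits what can be seen of weakly expressed genes.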

Other observations

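The subsets and tests of explanations in this part were all chosen after the results were seen.

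The integrated stress list split into groups of genes that did not move alike with KHS101. The list holds 7 aminoacyl-tRNA synthetases, which charge transfer RNA with amino acids, and other synthetases were not examined as a group. All 7 were higher at 5 uM (median log2 difference 1.55, from 1.04 to 2.38), and 5 of 7 at 1.7 uM (median 1.19). Eprs1 had the largest difference, 2.38 and 2.18. All 4 measured amino acid transporters were higher at 5 uM (median 1.77). They were Slc7a5 at 1.77, Slc3a2 at 1.76, Slc7a1 at 1.01 and Slc7a11 at 4.88. Slc7a11 was added to this subset from the NRF2 list and is not in the integrated stress list. Of 5 measured serine, glycine and one-carbon enzymes, 3 were higher at 5 uM, and Shmt2 (1.43 and 1.29) and Mthfd2 (1.36 and 1.40) were lower with retinoic acid and forskolin (-1.04 and -1.16). Atf4 was higher by 1.95 and 1.73, Ddit3 by 3.60 and 2.52 and Cebpb by 3.86 and 2.29. In contrast, 0 of 10 measured chaperones and foldases of the endoplasmic reticulum passed 2-fold at 5 uM. Dnajb9 was at 0.97, just short of it, Dnajc3 at 0.72, Hspa5 at 0.42 and Manf at 0.37. Hsp90b1 was at -0.09, Pdia6 at -0.18, Calr at -0.39, Pdia4 at -0.39, Sdf2l1 at -0.52 and Creld2 at -0.54.

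One hypothesis is that an unfolded protein response of the endoplasmic reticulum is the whole cause of the higher stress genes. It was taken to need a chaperone median of about 1 or more, a size set after the results were seen and without a reference in these data. The chaperone median at 5 uM was -0.14 (from -0.54 to 0.97, percentile 20.7 among random lists). As a set they were not higher, which argues against a response that raises these chaperones together, for these arrays. The subset did not hold every member of the response: Xbp1, placed in another subset, was higher by 0.62 at 5 uM, short of 2-fold. A response of the endoplasmic reticulum that leaves these chaperones unchanged cannot be decided by their median and stays open. Another trigger of the ATF4 branch may be involved and was not tested.

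The higher stress genes and lower replication genes with KHS101 could come from a DMSO array unlike the other cultures, or at 5 uM from a culture unlike all others. Comparing KHS101 with retinoic acid and forskolin leaves the DMSO array out, and the median of the integrated stress list was 1.80 at 5 uM and 1.54 at 1.7 uM, which argues against both explanations for these genes. For the replication list it was -1.38 at 5 uM, which argues against the DMSO array as the whole cause there, but -0.42 at 1.7 uM (2 of 50 genes lower), against -1.25 from DMSO. For replication genes a DMSO array unlike the others at 1.7 uM and a 5 uM culture unlike all others therefore stay open, since retinoic acid with forskolin itself had a median of -0.88 from DMSO. An effect of the compound and a difference that both KHS101 cultures share for another reason stay open, since treatment was not replicated within a concentration; neither was tested.

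The oligodendrocyte list had a median of -1.18 at 5 uM (9 of 13 genes lower), -0.55 at 1.7 uM (3 of 13 lower) and 0.37 with retinoic acid and forskolin (4 of 14 higher), so at 1.7 uM and with the positive control most members did not pass 2-fold. KHS101 5 uM against retinoic acid with forskolin leaves the DMSO array out and had a median of -1.54 (12 of 14 genes lower, 0 higher). At 1.7 uM the median was -0.97 (7 of 14 lower, 0 higher). The DMSO array is therefore not the source of the difference between these treatments. The opposite differences from DMSO already fix the direction of this comparison. It cannot decide whether the genes were lower with KHS101 or only higher with retinoic acid and forskolin. KHS101 5 uM against 1.7 uM also leaves the DMSO array out and had a median of -0.60 (1 of 12 genes lower, 0 higher). The DMSO array is therefore not the source of the step between the concentrations. As the cause of the lower values at 1.7 uM, and of the rest of the difference at 5 uM, a DMSO array unlike the other cultures stays open. Fewer cells of that lineage and lower expression per cell both stay open and were not tested.

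A full retinoic acid response with KHS101, raised by the higher Dhrs3 and Rarb, was tested as a hypothesis. The list had a median of -0.70 in KHS101 5 uM against retinoic acid with forskolin (4 of 12 genes lower, 0 higher). The medians from DMSO, 0.18 and 0.57, already gave this direction. Cyp26a1 had the largest bound upward with retinoic acid and forskolin, at least 104-fold from DMSO. It stayed under the floor on both KHS101 arrays. These arrays argue against a response as large as that of the positive control, which also held forskolin. A partial response stays open.

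At 5 uM the replication list lay below the mitosis list: the difference of medians was -0.82 (percentile 0 among 10000 random relabellings of their members), against -0.10 at 1.7 uM (percentile 2.23) and -0.19 with retinoic acid and forskolin (percentile 0). No explanation was tested, and no measure of cell-cycle phase was analysed here.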
